A study of Mus musculus with 17 samples.

How the data were processed

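CD8 T cells from mouse lung tumours were profiled by bulk RNA sequencing in 17 libraries. Per the labels, the cells came from WT mice or from mice lacking PD-L1 in the endothelium, which the labels call KO, and from core-enriched tissue (macroscopic nodules) or rim-enriched tissue (parenchymal nodules). The labels' protocols name the Qiagen RNeasy Micro Kit for RNA and the Illumina TruSeq RNA Library Prep Kit for libraries. Strandedness and the purity of the sort are not given in the sources used here. The submitters' processing notes name cutadapt 3.2, Bowtie2 2.4.5, HISAT2, Subread 2.0.0 and featureCounts, and the genome builds GRCm38 and mm10, without their order or settings.

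The authors deposited 1 table of raw read counts per gene symbol, with no normalization. It holds 27240 symbols, none repeated and none at 0 in all 17 libraries, and each column belongs to 1 labelled sample. All 27240 symbols matched the RefSeq annotation of GRCm38, from which chromosomes and positions were taken. Of the genes on the fixed lists, Ighd, Ighm, Igkc, Iglc2, Tagln, Trac, Trbc1 and Trbc2 have no entry in the table. Totals ran from 21767045 to 32566456 counts per library. At the group level, 3 counts summed over a group corresponded to 0.0683 CPM in WT rim, 0.0229 in WT core, 0.0184 in KO core and 0.0321 in KO rim, and this served as the floor for genes at 0. Floors cover counting error only, because reads without molecular identifiers are not independent molecules.

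Libraries were grouped by genotype and site as labelled: 5 WT core, 6 KO core, 2 WT rim and 4 KO rim. Nothing in the labels says that the libraries came from separate animals, so each p-value measures an effect against the spread between libraries. F322, F86 and O appear as identifiers in both KO core and KO rim. The labels do not say that identifiers mark animals, and no block was used in the main test. Reads from Xist and from Y-linked genes showed both F322 and both O libraries to be male, the WT core pool to be mixed, and the other libraries to be female.

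Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 20137, and libraries were scaled by TMM factors. A quasi-likelihood model with robust dispersion was fitted to all 17 libraries in 1 fit, so that WT rim, with 2 libraries, shared the spread of the other groups. Tested by the two-sided quasi-likelihood F test were KO against WT in core, KO against WT in rim, core against rim in KO, core against rim in WT, and the difference of the genotype effect between core and rim. P-values were adjusted by Benjamini-Hochberg over all 20137 genes, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. The log2 CPM of each library used a prior count of 2, while fitted log2 fold changes used the default of edgeR. Group levels are mean CPM with the SD between libraries.

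Groups of genes were tested on 30 lists: inhibitory receptors and exhaustion markers, exhaustion-associated transcription factors, stem-like and memory genes, cytotoxic effector genes, effector cytokines and chemokines, terminal effector and circulating genes, tissue residency genes, co-stimulatory receptors, T cell receptor response genes, chemokine receptors and integrins, cell cycle genes, type I interferon response genes, interferon gamma response and antigen presentation genes, glycolysis and hypoxia genes, oxidative phosphorylation genes, cytosolic ribosomal protein genes, ligands of PD-1 and of the CD28 family, dissociation stress and immediate early genes, T cell and CD8 identity markers, sex-linked genes, and markers of 10 other cell types or lineages (CD4 and regulatory T cells, natural killer cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells and MHC class II, lung epithelium and tumour, endothelium, fibroblasts and mural cells, red blood cells). The test was camera (limma 3.58.1) on the edgeR fit, two-sided, with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 30 lists of a comparison. The same test with an estimated correlation, and fry, which tests whether a list's genes move on balance 1 way, were run beside it. Members were counted as passing over all genes tested and as passing when adjusted over the list alone. Some lists share genes: 10 of the 18 measured T cell receptor response genes and 2 of the 6 measured CD4 and regulatory T cell markers are also on another list. The mean log2 CPM over each list was compared between groups by two-sided exact permutation tests. For the 10 marker lists these were adjusted by Benjamini-Hochberg over the 10 marker lists.

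Genes were named by a rule. For each comparison of 2 groups it takes the 10 called genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no clone, microRNA or pseudogene symbol. It adds up to 4 members of each list with the smallest p, and always Cd274, Pdcd1, Tox, Tcf7, Havcr2, Gzmb, Ifng and Mki67. For the difference of genotype effects it takes up to 10 called genes by smallest p. A gene named outside the rule is stated to have been chosen after its values were seen. The groups, comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined, except where an alternative is stated to have been added later.

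Alternatives were DESeq2 size factors in the same fit, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter at 5 CPM, limma voom with the identifier as a random block, limma voom with quality weights, covariates for sex and for markers of other cell types, fits of the 2 groups alone, fits of the 6 KO libraries with shared identifiers with and without a block, and leaving out each library in turn. Fits of the female libraries alone, and with the mean level of macrophage markers as a covariate, were added after seeing the data. Group labels were also exchanged among the libraries of each comparison of 2 groups. The edgeR test, camera with both correlations and fry were tried before use on simulated data with known changes, with genes drawn independently. The other tests were not. Chromatin, protein and cell number data were not used here.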

Results

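Transcript levels were measured by RNA sequencing in CD8 T cells sorted from lung tumours of WT mice and of mice without endothelial PD-L1, the ligand of the inhibitory receptor PD-1. The 17 libraries comprised 5 from WT core tissue, 6 from KO core tissue, 2 from WT rim tissue and 4 from KO rim tissue. Total counts in WT core were 26267638 in F164, 24642472 in H719, 26007316 in H873, 28517265 in H876 and 24207723 in the pool. In KO core they were 28149598 in F219, 29665490 in F318, 24702870 in F319, 23250676 in F322, 24590830 in F86 and 32566456 in O. In WT rim they were 23105415 in H874 and 21986257 in H877, and in KO rim 21767045 in F15, 23660218 in F322, 24690274 in F86 and 23736149 in O. The 50 most abundant genes took between 11.6 and 14.1 percent of the counts of a library. Correlations of log2 CPM between libraries ran from 0.884 to 0.945, with a median of 0.927 within groups and 0.919 between groups.

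Cd274, which encodes PD-L1 (chromosome 19, 29362107 to 29388095, GRCm38), was expressed in every library. In WT core it stood at 156 CPM in F164, 120 in H719, 114 in H873, 220 in H876 and 155 in the pool. In KO core it stood at 212 CPM in F219, 108 in F318, 87.8 in F319, 133 in F322, 125 in F86 and 162 in O. In WT rim it stood at 126 CPM in H874 and 194 in H877, and in KO rim at 171 in F15, 133 in F322, 156 in F86 and 152 in O. Its log2 fold change (KO over WT) was -0.15 (SE 0.212) in core and -0.063 (SE 0.303) in rim, neither past the test. Cd274 in CD8 T cells does not check the deletion, which was made in endothelial cells.

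The first comparison asked how loss of endothelial PD-L1 altered CD8 T cells in core-enriched tissue. Pdcd1, Tox, Havcr2, Tcf7, Gzmb, Ifng and Mki67 differed between KO and WT core by less than their standard error. Pdcd1, which encodes PD-1 (chromosome 1, 94038305 to 94052553), reached 1030 ± 412 CPM (SD, n = 6) in KO and 1010 ± 523 CPM (n = 5) in WT, a log2 fold change of 0.032 (SE 0.359). Tox, a transcription factor of exhausted T cells (chromosome 4, 6686353 to 6991557), had a log2 fold change of 0.19 (SE 0.278), Havcr2 0.057 (SE 0.342), Tcf7 0.014 (SE 0.334), Gzmb 0.21 (SE 0.286), Ifng -0.23 (SE 0.307) and Mki67 -0.20 (SE 0.317). No gene passed edgeR's test over 20137 genes, with 1244 at an unadjusted p under 0.05. Evenly spread p-values would give 1007, and other exchanges of the group labels in core gave a median of 1154. DESeq2 called 12 genes, 5 higher and 7 lower in KO, and limma voom with a block or with quality weights called 0. Among the genes at the smallest adjusted p, 0.796, was Cd40lg, which encodes a ligand made mostly by helper T cells. It measured 2 ± 0.823 CPM (SD, n = 6) in KO core and 6.08 ± 1.64 CPM (n = 5) in WT core, a log2 fold change of -1.60 (SE 0.352), and passed when adjusted over the list alone among the co-stimulatory receptors and among the CD4 and regulatory T cell markers.

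By camera with its preset correlation, 10 of the 30 lists passed in core, 1 higher and 9 lower in KO, and none of the 10 passed with an estimated correlation or by fry. The higher list was the type I interferon response (median log2 fold change 0.16, 23 of 30 members positive, adjusted p = 0.00208, and adjusted p = 0.727 with an estimated correlation). Among its members, Ifit1 measured 45.2 CPM in KO and 27.3 CPM in WT, and Cmpk2 30.5 CPM and 15 CPM. The camera call ended without WT core H719 (adjusted p = 0.0805) or KO core F219 (adjusted p = 0.053). Cell cycle genes were lower in KO (median -0.26, 32 of 35 members negative, adjusted p = 5.81e-06, and 0.727 with an estimated correlation), a call that ended without WT core H719 (adjusted p = 0.0883). Oxidative phosphorylation genes had a median of -0.10 (adjusted p = 0.000101), glycolysis genes -0.085 (adjusted p = 0.0102) and ribosomal protein genes -0.082 (adjusted p = 0.00865), each with adjusted p = 0.727 with an estimated correlation. The glycolysis call ended without WT core H719 (adjusted p = 0.112) or H873 (0.0873), and the ribosomal call without WT core H719 (0.119), the WT core pool (0.22) or KO core F318 (0.98). The ribosomal list's direction was not stable, since its mean log2 fold change turned to 0.0359 without F318 and to 0.0604 among female libraries (adjusted p = 0.996).

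Markers of other cells moved with these groups in core. B and plasma cell markers were lower in KO (median -0.905, 11 of 11 members negative, camera adjusted p = 1.24e-07), as were neutrophil markers (median -0.91, adjusted p = 2.87e-05), red blood cell markers (median -0.90, adjusted p = 0.00161) and macrophage markers (median -0.40, 17 of 18 negative, adjusted p = 0.00685), all with adjusted p = 0.727 with an estimated correlation. Cd79a, a B cell receptor component, measured 24.1 CPM in KO and 54.8 CPM in WT, and S100a8, abundant in neutrophils, 17.5 CPM and 45.9 CPM. The red blood cell call ended without KO core F318 (adjusted p = 0.0595), and the macrophage call without WT core F164 (0.0823), H873 (0.0873) or H876 (0.118), without KO core F86 (0.0762), and with the covariate for other cell types (0.868). That covariate is a mean over the markers of other cell types, macrophage markers included. The loss of the macrophage call with it therefore decides nothing. CD4 and regulatory T cell markers were lower in KO (median -0.485, 5 of 6 negative, adjusted p = 0.00121, and adjusted p = 0.081 with an estimated correlation). Their mean level was 3.45 ± 0.262 log2 CPM (SD, n = 6) in KO core and 4.01 ± 0.162 (n = 5) in WT core, a difference of -0.56 with an exact permutation p of 0.00433 and an adjusted p of 0.0433 over the 10 marker lists. With the median over the list in place of the mean the difference was -0.325 and did not pass (exact permutation p = 0.136, adjusted p = 0.453). Cd4 itself, chosen after its values were seen, was not lower. It measured 46.3 ± 47.2 CPM (SD, n = 6) in KO core and 41.1 ± 31.2 CPM (n = 5) in WT core. The level over all markers of other cell types differed by -0.39 log2 CPM between KO and WT core (exact permutation p = 0.314).

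The remaining lists did not pass in core. Their median log2 fold changes were -0.090 for inhibitory receptors (10 of 14 negative), 0.023 for exhaustion-associated transcription factors, 0.10 for stem-like genes, 0.16 for cytotoxic genes, -0.17 for effector cytokines, 0.10 for terminal effector genes, -0.092 for residency genes, -0.051 for co-stimulatory receptors, -0.026 for T cell receptor response genes, 0.055 for chemokine receptors and 0.13 for the interferon gamma response. They were -0.44 for the PD-1 and CD28-family ligands, 0.059 for dissociation stress genes, 0.030 for T cell identity, 0.515 for natural killer, -0.48 for dendritic cell, 0.26 for epithelial, -0.32 for endothelial, 0.050 for fibroblast and 2.66 for sex-linked genes, where camera pointed lower for the last 2.

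In rim-enriched tissue the same question concerned 4 KO and 2 WT libraries. Inhibitory receptors, T cell receptor response genes and effector cytokines were higher as groups in KO rim, while no single gene passed the test. Pdcd1 reached 1070 ± 34.1 CPM (SD, n = 4) in KO rim, and 236 CPM in H874 and 399 CPM in H877 of WT rim, a log2 fold change of 1.75 (SE 0.559, edgeR adjusted p = 0.45). Lag3, another inhibitory receptor (chromosome 6, 124904359 to 124912434), measured 84.7 ± 25.5 CPM and 17.5 ± 12.3 CPM (log2 fold change 2.27, SE 0.517, adjusted p = 0.229). Tnfrsf9, an activation-induced co-stimulatory receptor also called 4-1BB (chromosome 4, 150920155 to 150946104), measured 204 ± 57 CPM and 32.7 ± 3.63 CPM (2.64, SE 0.478, adjusted p = 0.0866). Xcl1, a chemokine that attracts dendritic cells (chromosome 1, 164931644 to 164935522), measured 82.9 ± 43.1 CPM and 11.6 ± 5.45 CPM (2.83, SE 0.467, adjusted p = 0.061). For Pdcd1, Lag3, Tox, Havcr2, Ifng, Tnfrsf9, Xcl1 and Mki67, both WT rim libraries lay below all 4 KO rim libraries, while Cd274, Tcf7 and Gzmb did not show this order. The plot of CPM per library for 8 genes shows this separation and the overlap in core.

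**Figure D1:**
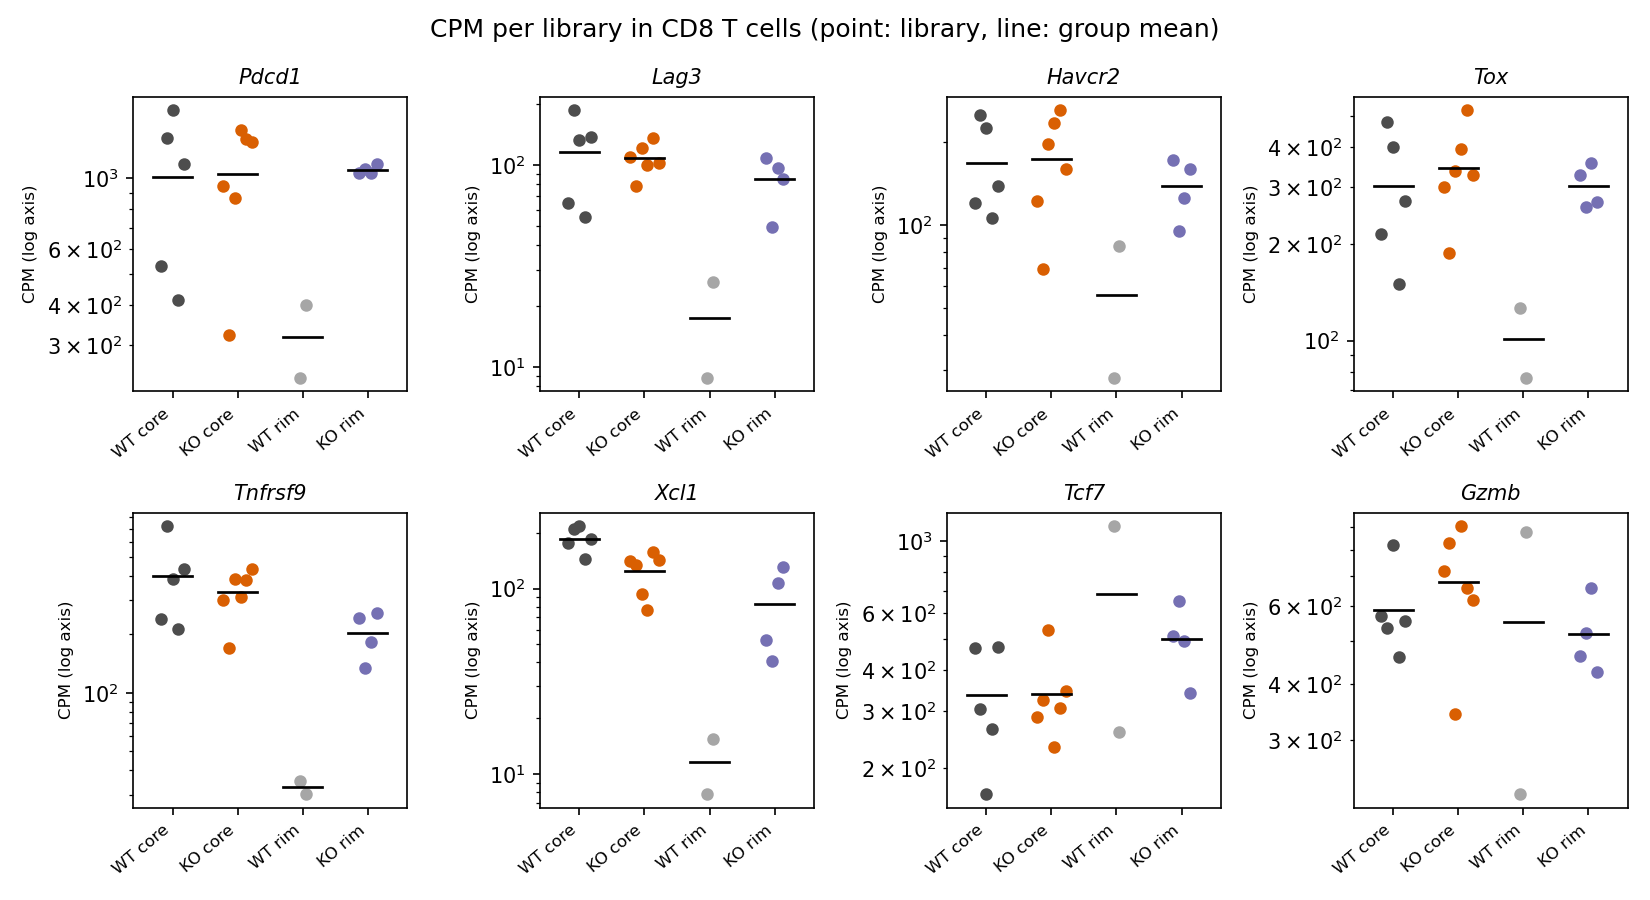
Expression (CPM, log axis) of Pdcd1, Lag3, Havcr2, Tox, Tnfrsf9, Xcl1, Tcf7 and Gzmb in each group, with points for libraries and lines for group means. Except for Tcf7 and Gzmb, the 2 WT rim libraries (236 and 399 CPM for Pdcd1) sit below the 4 KO rim libraries (1040 to 1110 CPM), while WT and KO core libraries overlap.

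No gene was called by edgeR in rim, where the smallest adjusted p was 0.0541 and 1480 genes had an unadjusted p under 0.05. DESeq2 called 272 genes, 256 higher and 16 lower in KO, and limma voom called 8 with a block and 6 with quality weights, all lower. The edgeR count was 4 without WT rim H874, 23 without WT rim H877 and 26 without KO rim F322. The genes at an adjusted p of 0.0541 were Npl, Pvrig and Glp1r, all chosen after their values were seen.

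In rim 14 of the 30 lists passed with the preset correlation, 3 with an estimated correlation and 4 by fry. Of the 14 inhibitory receptors and exhaustion markers, 10 were higher in KO rim and 1 lower when adjusted over the list alone, and none passed over all genes (median log2 fold change 1.42, camera adjusted p = 3.06e-16, and adjusted p = 0.0172 with an estimated correlation). The 10 included Cd38 (1.33, SE 0.276), Cd101 (1.52, SE 0.348) and Cd200r1 (2.33, SE 0.55), and the 1 that was lower was Vsir, chosen after its values were seen. T cell receptor response genes rose as a list (median 0.68, 15 of 18 positive, adjusted p = 0.0226 with an estimated correlation). Of these, Tnfrsf9 and Tnfrsf4 passed when adjusted over the list alone. Effector cytokines rose as a list (median 1.09, 11 of 13 positive, adjusted p = 0.0371 with an estimated correlation), with Xcl1 passing over the list alone. Without WT rim H874 camera no longer called the cytokines (adjusted p = 0.171). Ifng measured 200 ± 60.3 CPM (SD, n = 4) in KO rim and 94.1 ± 61.8 CPM (n = 2) in WT rim.

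Cell cycle genes were higher in KO rim by camera with the preset correlation (median 1.15, 34 of 35 positive, adjusted p = 2.22e-27), with 21 of 35 passing when adjusted over the list alone, and had adjusted p = 0.112 with an estimated correlation. Mki67, a proliferation marker (chromosome 7, 135689784 to 135716450), measured 72.8 ± 26.2 CPM (SD, n = 4) in KO and 30.5 ± 10.6 CPM (n = 2) in WT, and Ccnb2, a mitotic cyclin, 57 ± 19.5 CPM and 19.3 ± 3.33 CPM. Exhaustion-associated transcription factors were higher (median 0.65, 13 of 14 positive, adjusted p = 3.09e-06, and adjusted p = 0.0664 with an estimated correlation), and Tox (1.58, SE 0.428) and Tox2 (2.63, SE 0.743) passed over the list alone. Glycolysis genes were higher (median 0.26, adjusted p = 2e-04, and 0.227 with an estimated correlation), with Aldoa, Tpi1, Pgk1, Pgam1 and Pkm passing over the list alone, of which Pkm was chosen after its values were seen. Co-stimulatory receptors (median 0.32, adjusted p = 0.258 with an estimated correlation) ended as a camera call without WT rim H877 (adjusted p = 0.0815). Residency genes (0.24, 0.167 with an estimated correlation) ended without WT rim H874 (0.471). Terminal effector genes were lower (median -0.83, 12 of 14 negative, camera adjusted p = 1.64e-05, and 0.167 with an estimated correlation), and that call ended without WT rim H877 (mean log2 fold change 0.206, adjusted p = 0.638).

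Type I interferon genes (median 0.31, camera adjusted p = 0.00229, and 0.34 with an estimated correlation), interferon gamma genes (0.14, adjusted p = 0.0409, and 0.53) and dissociation stress genes (0.375, adjusted p = 0.0138, and 0.308) were also higher with the preset correlation. Isg20 passed over the interferon list alone, and Hspa8, Hspa1a and Hspa1b passed over the stress list alone, where the last pair are near-identical and uncertain. Each of these calls ended without WT rim H877 (adjusted p of 0.159, 0.127 and 0.169) and without KO rim F86 (0.116, 0.222 and 0.13). The interferon gamma call also ended without KO rim F15 (0.0765), and it and the stress call ended without WT rim H874 (0.0653 and 0.0934).

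Macrophage markers moved with these groups in rim (median 1.49, 17 of 18 positive, camera adjusted p = 0.000375, and adjusted p = 0.534 with an estimated correlation). C1qb, a complement component made by macrophages, measured 165 ± 152 CPM (SD, n = 4) in KO rim and 22.6 ± 8.92 CPM (n = 2) in WT rim. The macrophage call ended without WT rim H874 (adjusted p = 0.128) or KO rim O (0.137). Fibroblast markers had a median of 2.18 (adjusted p = 0.0378, and 0.534 with an estimated correlation), a call that leaving out either WT rim library (0.103 without H874, 0.221 without H877), KO rim F15 (0.282) or KO rim O (0.0704) ended. The level over all markers of other cell types differed by 0.23 log2 CPM between KO and WT rim (exact permutation p = 0.933, where the smallest possible is 0.0667).

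The remaining lists did not pass in rim, and for 3 of them camera's direction turned without 1 WT rim library. Without H874 camera called stem-like genes higher (mean log2 fold change 0.507, adjusted p = 0.0281) and ribosomal protein genes higher (0.476, adjusted p = 6.76e-10), and without H877 cytotoxic genes higher (0.596, adjusted p = 0.00804). Neutrophil markers turned to -0.908 with the macrophage covariate (adjusted p = 0.00604). With all libraries, stem-like genes had a median of -0.52, and Tcf7, a factor of stem-like T cells, measured 499 ± 128 CPM (SD, n = 4) in KO and 685 ± 604 CPM (n = 2) in WT. Cytotoxic genes had a median of -0.30 with a mean of 0.12, and Gzmb a log2 fold change of -0.093 (SE 0.406). Medians were 0.075 for chemokine receptors, 0.076 for oxidative phosphorylation, -0.165 for ribosomal protein, 0.14 for T cell identity, 0.68 for CD4 and regulatory T cell, 0.42 for natural killer, -0.53 for B cell, 0.525 for neutrophil, -0.62 for dendritic cell and 1.73 for epithelial genes (17 of 17 positive, camera adjusted p = 0.0523). The mean epithelial level was high in KO rim O, at 4.36 log2 CPM. It was 0.906 in KO rim F15, 0.361 in F322 and -0.494 in F86, and 0.49 in H874 and 0.708 in H877 of WT rim. PD-1 and CD28-family ligands had a median of -0.064 with a mean of 0.68. Endothelial markers had a median of 0.13 and red blood cell markers 0.0080, both with camera pointing lower. Sex-linked genes had a median of 12.2, or 8.38 with genes at 0 set to their bound, since KO rim held male libraries and WT rim did not.

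The comparison of core with rim in WT mice concerned how the tissue sampled, core-enriched or rim-enriched, related to T cell state. No WT identifier appeared in both. Core cells had more transcripts of cell cycle, glycolysis, inhibitory receptor and effector cytokine genes than rim cells, and fewer of S1pr1 and S1pr4, receptors for the lipid that guides T cells out of tissue. Xcl1 measured 186 ± 29 CPM (SD, n = 5) in core and 11.6 ± 5.45 CPM (n = 2) in rim, a log2 fold change of 4.0 (SE 0.494, adjusted p = 0.00195). Tpi1, a glycolytic enzyme (chromosome 6, 124810586 to 124814158), measured 424 ± 78 CPM and 78.8 ± 8.02 CPM (2.43, SE 0.307, adjusted p = 0.00195). Ccnb2 (chromosome 9, 70407689 to 70421554) measured 128 ± 38.3 CPM and 19.3 ± 3.33 CPM (2.73, SE 0.379, adjusted p = 0.00253). S1pr1 (chromosome 3, 115710433 to 115715055), fell from 1520 ± 697 CPM in rim to 397 ± 131 CPM in core (log2 fold change -1.94, SE 0.307, adjusted p = 0.00492).

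In all, 777 genes differed in WT, 422 higher and 355 lower in core, of which 455 changed at least 2-fold, with 3617 at an unadjusted p under 0.05. DESeq2 called 1853 genes, 776 of them among the 777. The count depended most on WT rim H874, with 68 genes without it (50 of them among the 777) and 687 without H877 (349 among the 777), and was 91 in a fit of the 2 groups alone. It was 411 without WT core H873, 500 without WT core H719, 139 by limma with quality weights, 313 among female libraries and 183 with the macrophage marker level as a covariate (171 among the 777), the last 2 added after seeing the data. Of the named genes called in WT, 51 were lost without H874, 26 without H877, 23 without H873, 17 without H719, 15 without the pool, 11 without F164 and 7 without H876. Xcl1, Tpi1, Aldoa, Pgk1, Pkm, Ccnb2, Tnfrsf9, S1pr4 and Ier2 were called in each of these fits.

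In WT 15 of the 30 lists passed with the preset correlation, 5 with an estimated correlation and 9 by fry. Cell cycle genes rose in WT core, 25 of 35 over all genes and 31 of 35 adjusted over the list alone, with 35 of 35 positive (median 2.16, adjusted p = 0.0415 with an estimated correlation). Examples were Tk1 (2.79, SE 0.468), Cdk1 (2.65, SE 0.453) and Mki67 (2.25, SE 0.503). Glycolysis genes rose, 10 of 27 over all genes and 11 over the list alone (median 0.585, adjusted p = 0.0329 with an estimated correlation), among them Aldoa (1.17, SE 0.143), Pgk1 (1.59, SE 0.201) and Pkm (1.06, SE 0.146). Of the 14 inhibitory receptors and exhaustion markers, 6 rose and 1 fell over all genes, and 11 rose and 1 fell over the list alone (median 1.67, adjusted p = 0.0329 with an estimated correlation). Cd160 (1.99, SE 0.324), Cd38 (1.69, SE 0.276) and Cd200r1 (3.22, SE 0.572) rose, whereas Pdcd1 (1.66, SE 0.546) and Havcr2 (1.58, SE 0.518), each with adjusted p = 0.103, did not pass over all genes. The member that fell was Vsir, chosen after its values were seen. Mki67, Cd160, Cd38, Cd200r1, Tk1, Cdk1 and S1pr1 were no longer called without WT rim H874 (adjusted p from 0.0782 for Cd160 to 0.267 for Mki67), and their directions stayed.

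Effector cytokines rose in WT core (median 1.23, 12 of 13 positive, adjusted p = 0.0408 with an estimated correlation), with Xcl1 and Ccl3 (2.99, SE 0.737) past the threshold over all genes and 6 over the list alone. Without either WT rim library, WT core H719 or WT core H873, Ccl3 was not called (adjusted p from 0.0512 without H719 to 0.349 without H874). CD4 and regulatory T cell markers rose (median 1.56, adjusted p = 0.0415 with an estimated correlation) with Il2ra, which is also an activation gene of CD8 T cells, and Izumo1r past the threshold over all genes. Their camera call ended without WT rim H874 (adjusted p = 0.0569), as did the gene call of Il2ra (0.287), while Izumo1r was lost without WT rim H877 (0.238) and without WT core F164, H719, H873 or the pool (adjusted p from 0.0578 to 0.0821). Cd4 itself, chosen after its values were seen, did not rise. It measured 41.1 ± 31.2 CPM (SD, n = 5) in WT core and 56.1 ± 72.6 CPM (n = 2) in WT rim. T cell receptor response genes were higher by the preset correlation (median 0.36, adjusted p = 0.00115, and 0.106 with an estimated correlation). Among them Tnfrsf9 (3.61, SE 0.5), Tnfrsf4 (3.41, SE 0.512) and Il2ra were called. Tnfrsf9 and Tnfrsf4 were also the 2 called co-stimulatory receptors (median 0.27, adjusted p = 0.0352, and 0.66 with an estimated correlation), a list call that ended without WT rim H877 (0.485), H719 (0.0673), H873 (0.0552) or the pool (0.127). Without WT rim H874 the adjusted p of Tnfrsf4 was 0.0541. Tox (1.58, SE 0.42, adjusted p = 0.0462), Tox2 (2.98, SE 0.747, adjusted p = 0.0362) and Rbpj (1.53, SE 0.412, adjusted p = 0.0481) were the 3 of 14 exhaustion-associated transcription factors that rose (median 0.26, camera adjusted p = 0.042, and 0.459 with an estimated correlation). The list's call ended without H874 (0.186), H719 (0.129) or H873 (0.0633). Each of the 3 genes was lost without H874 (0.161, 0.14 and 0.309), H877 (0.248, 0.197 and 0.163), H719 (0.0849, 0.0616 and 0.0891) or H873 (0.0844, 0.0665 and 0.0802).

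Terminal effector and circulating genes fell in WT core, 3 of 14 over all genes and 6 over the list alone (median -1.13, camera adjusted p = 2.95e-08, and 0.0656 with an estimated correlation). These were S1pr1, S1pr4 (-1.50, SE 0.205) and Klf3 (-1.75, SE 0.306), and the list's call ended without WT rim H877 (adjusted p = 0.073). Of 18 stem-like genes, S1pr1, Foxp1 (-1.16, SE 0.23) and Foxo1 (-1.11, SE 0.284) fell and Xcl1 rose, while 11 fell and 1 rose over the list alone (median -1.06, adjusted p = 4.92e-06, and 0.217 with an estimated correlation). Without WT rim H874 camera did not call the stem-like list (mean log2 fold change 0.00892, adjusted p = 0.434), nor did edgeR call Klf3 (0.115), Foxp1 (0.403) or Foxo1 (0.413). Tcf7 measured 334 ± 133 CPM (SD, n = 5) in WT core and 685 ± 604 CPM (n = 2) in WT rim and did not pass (adjusted p = 0.223). Oxidative phosphorylation genes were higher in core (median 0.36, 37 of 38 positive, 5 called and 21 over the list alone, adjusted p = 7.59e-10, and 0.192 with an estimated correlation). The 5 were Atp5j, Ndufb3, Cox8a, Atp5g1 and Uqcrb, the last chosen after its values were seen. Residency genes had a median of 0.69 (adjusted p = 0.00369, and 0.192 with an estimated correlation) and were not called without WT rim H874 (0.186). The plot of list levels per library shows the cell cycle, glycolysis, inhibitory and stem-like lists.

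**Figure D2:**
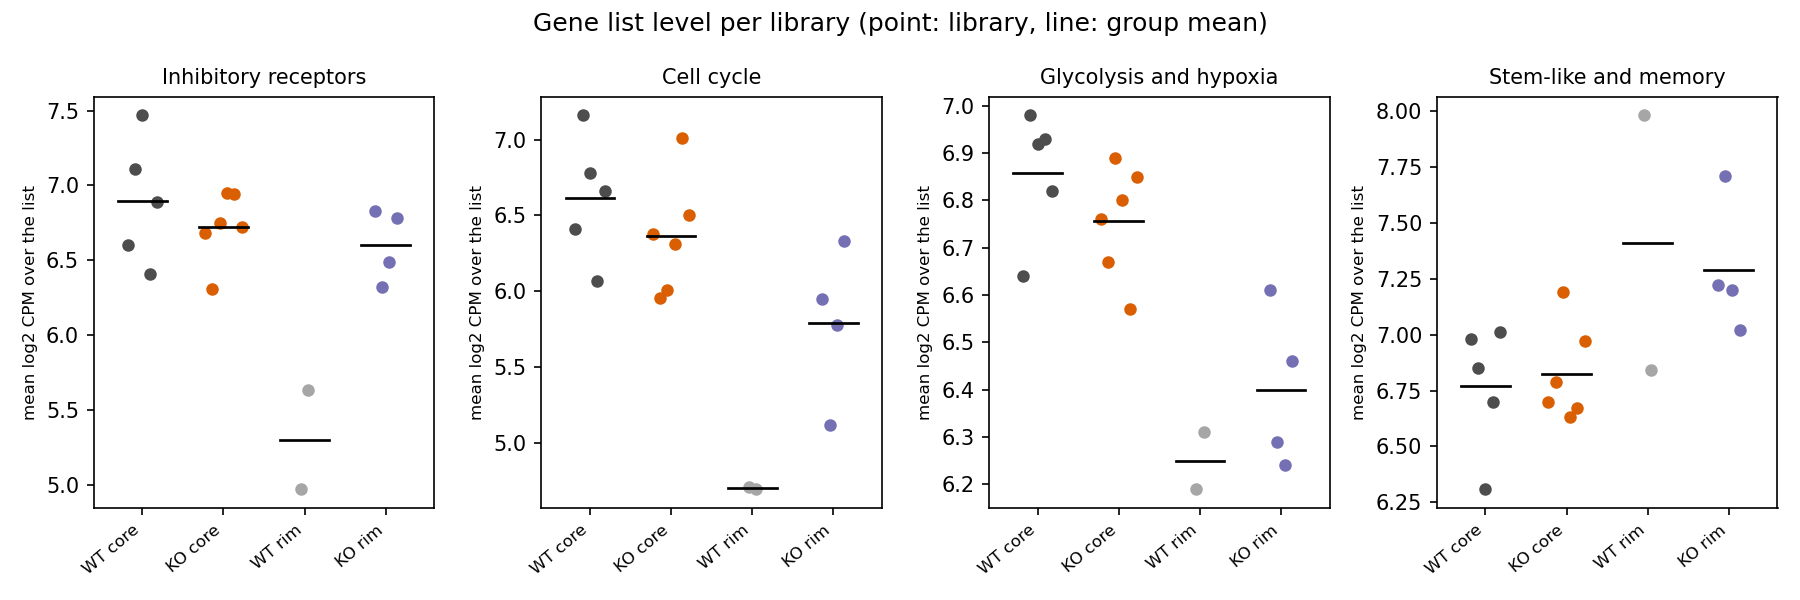
Mean log2 CPM over the inhibitory receptor, cell cycle, glycolysis and stem-like lists in each library (points), with lines for group means. WT rim libraries sit lowest for the inhibitory list, with a mean of 5.30 against 6.90 in WT core, 6.72 in KO core and 6.61 in KO rim.

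Macrophage markers moved with these groups in WT (median 1.83, 17 of 18 positive, camera adjusted p = 4.92e-06, and adjusted p = 0.459 with an estimated correlation), and C1qb (3.45, SE 0.848) and C1qc (3.45, SE 0.854) rose. C1qb was lost without H874 (adjusted p = 0.224), H877 (0.182) or H873 (0.0601), and C1qc without the same libraries (0.242, 0.182 and 0.0617). The mean level of macrophage markers was 6.42 ± 0.766 log2 CPM (SD, n = 5) in core and 4.66 ± 0.176 (n = 2) in rim, with an exact permutation p of 0.0476, the smallest that 21 splits allow, and an adjusted p of 0.119. Over all markers of other cell types the difference was 0.76 log2 CPM (exact permutation p = 0.143). Neutrophil markers (median 1.18, camera adjusted p = 0.00606, and 0.59 with an estimated correlation) and fibroblast markers (median 1.69, adjusted p = 0.042, and 0.626) were higher as well. The covariate for other cell types is made from these markers too, so a call of theirs lost with it decides nothing. The neutrophil call ended without WT rim H874 (0.135) and with the covariate for other cell types (0.244), and with the macrophage covariate its direction turned (mean log2 fold change -0.441, adjusted p = 0.43). The fibroblast call ended without WT rim H877 (0.246), without WT core F164 (0.0687), H876 (0.0848) or the pool (0.0581), and with that covariate (0.238).

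The largest rises in WT core among the named genes were in Rgs8 and Fcna, both at 0 counts in WT rim. By the WT core mean over the floor they were at least 241-fold and 101-fold higher. Among WT core libraries Rgs8 ran from 0.679 to 34.6 CPM and Fcna from 3.04 to 11.3 CPM. Other large rises were in Gja5, Glp1r (log2 fold change 8.07, SE 1.22), Gbp2b, Ppp2r2c, Clgn, Slc17a6, Spp1 and Ccl1. Spp1, an abundant transcript of tumour macrophages, had a log2 fold change of 5.97 (SE 1.29) over 5.09 ± 1.36 CPM (SD, n = 2) in rim, and was lost without H874 (adjusted p = 0.191) or H877 (0.111). Ccl1, a chemokine of activated T cells, measured 74.1 ± 24.1 CPM (SD, n = 5) in core and 1.43 ± 1.36 CPM (n = 2) in rim, with an adjusted p of 0.0521 without H874. Gbp2b is near-identical to a neighbour and uncertain. The largest falls were in Esm1, Bambi, Ankrd9, Ifngr2, Lncpint, Axin2, Rrad, Dstyk, S1pr1 and Gadd45a, from -2.58 for Esm1 to -1.90 for Gadd45a. Each of these 10 lost its call without a WT rim library. Esm1 stood at -0.58 without H877 (adjusted p = 0.737), and without H874 Ifngr2 stood at -0.446 (0.783), Lncpint at -0.954 (0.708), Rrad at -1.3 (0.326) and Dstyk at -1.24 (0.525). Of the 10 rises, Glp1r and Slc17a6 alone kept their call in every fit that left out 1 library. Ier2, an immediate early gene, fell from 991 ± 52.1 CPM in rim to 386 ± 36.2 CPM in core.

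The other lists did not pass in WT. Without WT rim H874 camera called cytotoxic genes lower (mean log2 fold change -0.0776, adjusted p = 0.0293) and ribosomal protein genes higher (0.525, adjusted p = 4.78e-10), each against camera's direction with all libraries. Chemokine receptors had a median of -0.35 with a mean of 0.17, and Ccr8 and Cxcr3 rose while Itgb7 fell. Type I interferon genes had a median of 0.11, with Isg20 up and Irf9 down, and interferon gamma genes 0.18, with Psmb8 and Psmb9 up and Irf1 down. Dissociation stress genes had a median of 0.32 with camera pointing lower, with Ier2 and Junb down and Hspa1b up. Pdcd1lg2, the second PD-1 ligand, was the 1 of 7 ligands that rose (1.77, SE 0.369, list median 0.335). Medians were 0.17 for cytotoxic, -0.14 for ribosomal protein, -0.023 for T cell identity, 0.55 for natural killer, -0.81 for B cell, 0.50 for dendritic cell, 1.43 for epithelial, 0.10 for endothelial and -0.023 for red blood cell genes, where T cell identity, endothelial and red blood cell lists differed in sign between median, mean or camera. Sex-linked genes had a median of 8.66, or 4.88 with genes at 0 set to their bound.

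In KO mice the same contrast of core with rim gave no called gene. Glycolysis genes stood higher in core by camera with the preset correlation but not with an estimated one (adjusted p = 0.141), with Pkm at 1360 ± 58.7 CPM (SD, n = 6) in core and 953 ± 157 CPM (n = 4) in rim (log2 fold change 0.52, SE 0.108, adjusted p = 0.572). S1pr1 stood lower, at 427 ± 103 CPM and 944 ± 245 CPM (-1.15, SE 0.249, adjusted p = 0.572). Pdcd1 (-0.053, SE 0.382) and Tox (0.19, SE 0.297) differed by less than their error. No gene was called by edgeR, 1600 had an unadjusted p under 0.05, DESeq2 called 33 (15 higher and 18 lower), and limma voom called 2 with a block and the same 2 with quality weights (Trpa1 and Rbms3, chosen after their values were seen).

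Of the 27 glycolysis genes, 22 were higher in KO core and 11 passed when adjusted over the list alone (median 0.34, camera adjusted p = 6.57e-10 with the preset correlation and 0.0196 by fry). Tpi1 measured 340 ± 32.5 CPM (SD, n = 6) in core and 184 ± 69.8 CPM (n = 4) in rim. Cell cycle genes (median 0.57, 33 of 35 positive, adjusted p = 5.84e-14) and oxidative phosphorylation genes (0.20, 37 of 38 positive, adjusted p = 1.96e-08) were higher by the preset correlation, each with adjusted p = 0.463 with an estimated correlation. Stem-like genes were lower (median -0.45, 16 of 18 negative, adjusted p = 1.91e-07, and 0.463 with an estimated correlation), with S1pr1, Foxp1 and Cxcr5 passing over the list alone. B cell markers moved with them (median -1.58, camera adjusted p = 8.36e-06, and 0.516 with an estimated correlation), with Cd79a at -1.58 (SE 0.639). Over all markers of other cell types core and rim differed by 0.14 log2 CPM (exact permutation p = 0.83). Camera called dissociation stress genes lower (adjusted p = 0.00409, and 0.463 with an estimated correlation) although their median was 0.038, with Ier2, Dnajb1, Dnaja1 and Junb lower over the list alone. That call ended without KO rim F86 (mean log2 fold change 0.0562, adjusted p = 0.203).

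Camera also called terminal effector genes lower (adjusted p = 0.0408 with a median of 0.023), co-stimulatory receptors lower (0.042, median -0.11), and natural killer (0.0459, median 0.58) and dendritic cell markers (0.0408, median 0.59) higher, each with adjusted p = 0.748 with an estimated correlation. These were kept in 5, 5, 5 and 6 of the 10 fits that left out a library. Among them, the co-stimulatory, natural killer and dendritic calls ended without KO core F318 (adjusted p of 0.353, 0.327 and 0.327) and the terminal effector call without KO rim F86 (0.37), where its mean log2 fold change turned to 0.0767. On the 6 libraries with shared identifiers the co-stimulatory list turned to 0.0571 with a fixed block (adjusted p = 0.251) and 0.0577 without (adjusted p = 0.491). The other lists did not pass, with medians of 0.165 for inhibitory receptors, -0.091 for exhaustion-associated transcription factors, 0.26 for cytotoxic genes, 0.49 for effector cytokines, 0.14 for residency genes, -0.035 for T cell receptor response genes, 0.063 for chemokine receptors, 0.030 for type I interferon, 0.065 for interferon gamma and -0.042 for ribosomal protein genes. They were 0.36 for PD-1 and CD28-family ligands, -0.058 for T cell identity, 0.275 for CD4 and regulatory T cell, -0.021 for macrophage, -0.40 for neutrophil, -0.023 for epithelial, -0.50 for endothelial, 0.35 for fibroblast, -0.999 for red blood cell and -0.565 for sex-linked genes. Median, mean or camera differed in sign for 8 of the 30 lists, of which 2 were called.

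Of the 422 genes higher in WT core, 398 (94.3 percent) had the same sign in KO, as did 349 of the 355 lower genes (98.3 percent). Their median log2 fold changes were 1.59 in WT and 0.335 in KO for the higher genes, and -0.98 in WT and -0.37 in KO for the lower genes. These genes were chosen in WT, so part of the difference in size follows from the choice. Across genes, which are not independent replicates, the site effects of WT and KO correlated at a Pearson r of 0.121 and a Spearman rho of 0.275 over all tested genes, and at 0.476 and 0.589 over the 10404 genes with a mean of at least 5 CPM. Of all tested genes 64.6 percent had the same sign in WT and KO, and 72.9 percent of these 10404.

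**Figure D3:**
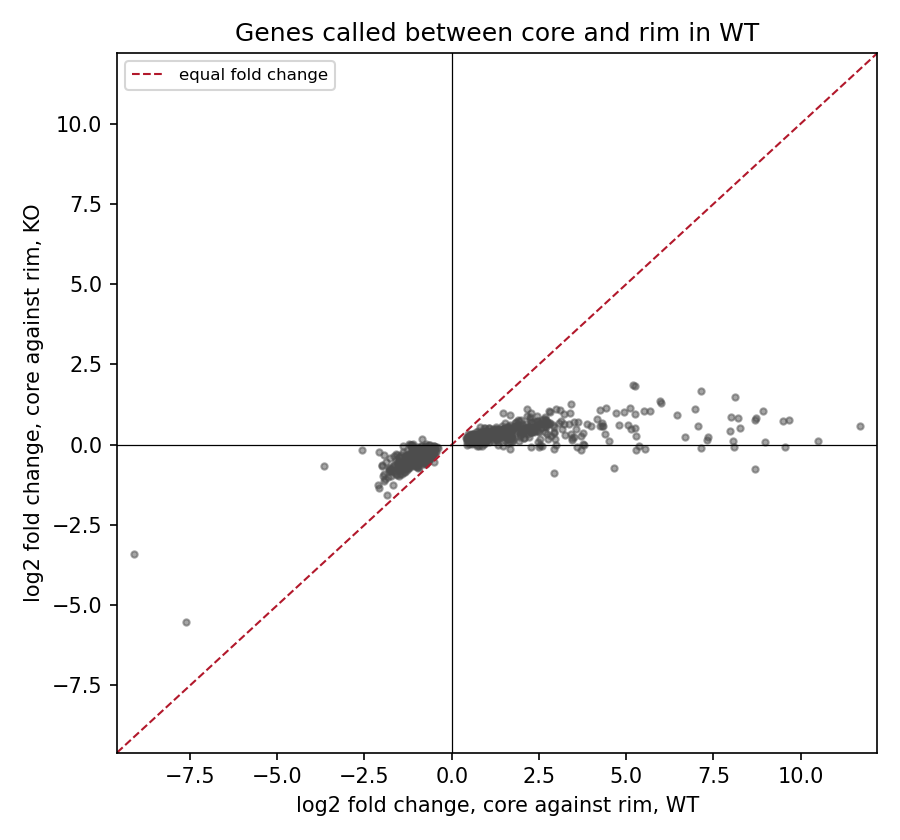
Log2 fold change of core over rim for the 777 genes called in WT, in WT (x axis) and in KO (y axis), with the dashed line at equal values. Most points share the sign of the WT effect (398 of 422 higher, 349 of 355 lower) and lie nearer 0 in KO. Over all tested genes 64.6 percent share a sign.

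The difference of the genotype effect between core and rim was tested directly. Inhibitory receptors, T cell receptor response genes, effector cytokines, and CD4 and regulatory T cell markers had a lower genotype effect in core than in rim as groups. For Pdcd1 the difference was -1.72 (SE 0.65, adjusted p = 0.586), for Tox -1.39 (SE 0.498, adjusted p = 0.572), for Mki67 -1.45 (SE 0.574, adjusted p = 0.592), for Havcr2 -1.25 (SE 0.613) and for Ifng -1.32 (SE 0.552). Tcf7 (0.47) and Gzmb (0.30) pointed the other way, and Cd274 stood at -0.084. No gene was called by edgeR (smallest adjusted p 0.0621), 1547 had an unadjusted p under 0.05, DESeq2 called 159 (10 higher and 149 lower) and limma voom called 0 with a block and 0 with quality weights. The edgeR count was 14 without WT rim H877 and 14 without KO rim F322, 5 without WT rim H874, 5 without WT core H876, 2 without the WT core pool and 1 without KO core F86.

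With an estimated correlation 4 lists passed, as many by fry and 14 with the preset correlation. The median difference was -1.48 for inhibitory receptors (12 of 14 negative, adjusted p = 0.0296), -0.56 for T cell receptor response genes (14 of 18 negative, adjusted p = 0.0303), -0.88 for effector cytokines (11 of 13 negative, adjusted p = 0.0303) and -1.26 for CD4 and regulatory T cell markers (5 of 6 negative, adjusted p = 0.0303). Over the list alone 10 of the 14 inhibitory receptors had a lower genotype effect in core. The cytokine call of camera ended without WT rim H874 (adjusted p = 0.121). Cell cycle genes (median -1.38, 34 of 35 negative, 24 over the list alone) had adjusted p = 1.41e-32 with the preset correlation and adjusted p = 0.0697 with an estimated correlation. Markers of other cells moved with these lists by the preset correlation: macrophage (median -1.73, adjusted p = 4.03e-06, and 0.468 with an estimated correlation), neutrophil (-1.71, adjusted p = 0.00392, and 0.54) and fibroblast markers (-1.47, adjusted p = 0.0106, and 0.508). The neutrophil call ended without WT rim H874 (0.231), KO rim F15 (0.0927) or KO rim O (0.0836), and the fibroblast call without WT rim H877 (0.137) or KO rim F15 (0.197, mean 0.0525). With the macrophage covariate the neutrophil difference turned to 0.531 (adjusted p = 0.545). Cytotoxic, chemokine receptor and endothelial lists differed in sign between median, mean or camera and did not pass. Of the lists that did not pass, leaving out 1 WT rim library turned camera's direction for 3, with ribosomal protein genes at a mean of -0.556 without H874 (adjusted p = 1.22e-12), and cytotoxic genes at -0.396 (0.00667) and dendritic cell markers at -1.76 (0.0195) without H877. Across genes, the genotype effects in core and in rim had a Pearson r of 0.031 and a Spearman rho of 0.024, and 49.3 percent of genes shared a sign. The plot of list medians in the 4 comparisons of 2 groups sets these values side by side. The rim genotype comparison, the WT site comparison and the difference of genotype effects share the 2 WT rim libraries, and values that rest on these are not independent.

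**Figure D4:**
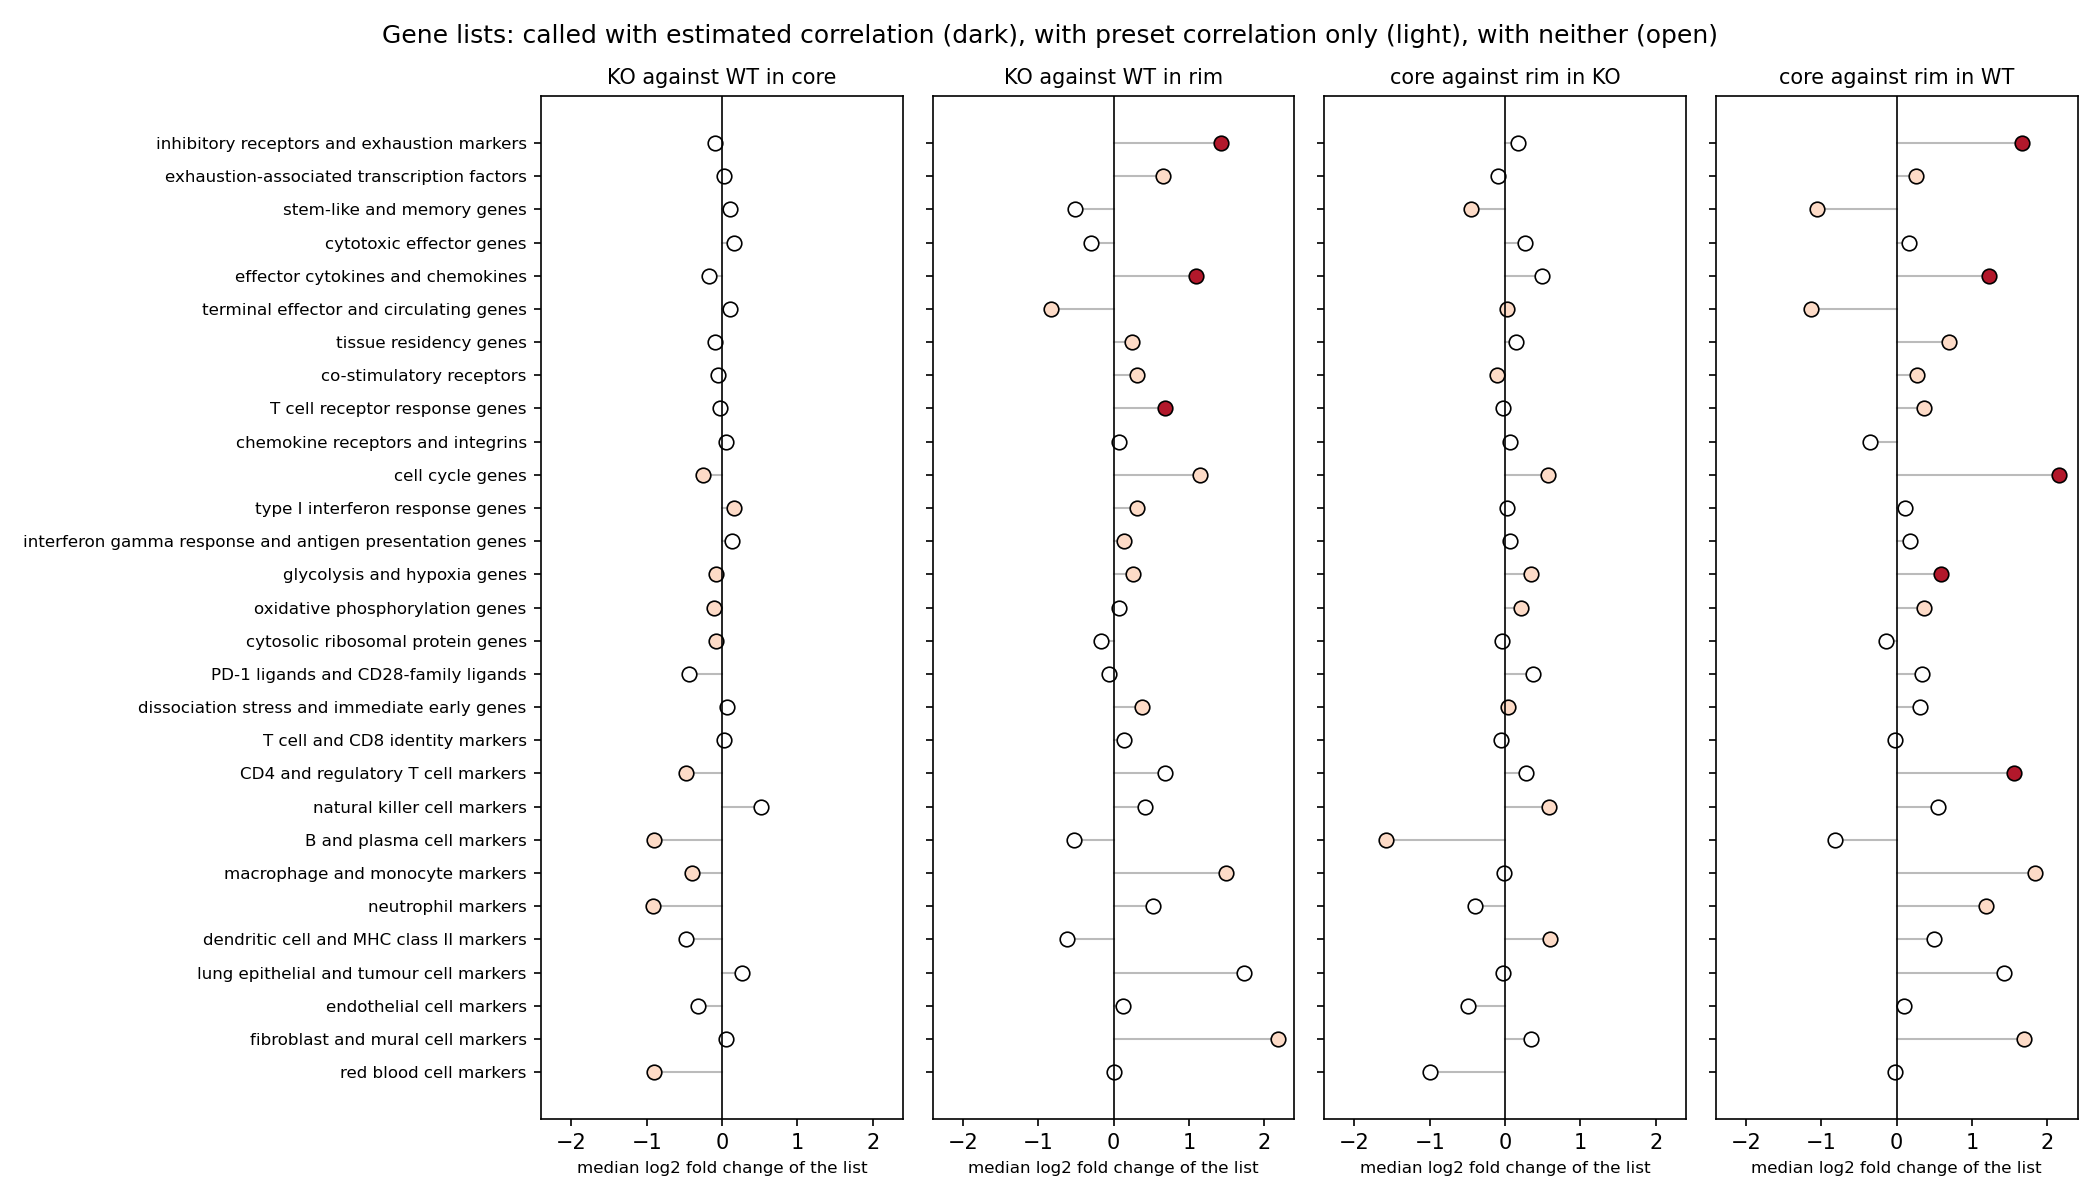
Median log2 fold change of 29 gene lists in the 4 comparisons of 2 groups, with dark points for lists called with an estimated correlation, light points for lists called with the preset correlation only and open points for the rest. The inhibitory receptor list lies at 1.42 for KO over WT in rim and 1.67 for core over rim in WT, and at -0.090 for KO over WT in core and 0.165 for core over rim in KO.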

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

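The tests of other splits of the libraries, of the WT rim pair and of co-variation of B cell markers were set before their results were seen, the last 3 kinds of split (both for KO against WT in rim, and lists in core against rim in WT) after the first splits had been seen. The tests of other cell types, of leaving out a library and of sex were chosen after the result was seen.

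Among WT mice 777 genes differed between core and rim. Of the 21 splits of these 7 libraries 1 gave as many, the real one, with 35 as the highest of the others. That share is under 0.05 but is the smallest that 21 splits allow (0.0476), so chance is not firmly excluded for this count. Of lists called with an estimated correlation the real split gave 5, with 1 of 21 splits as high and 1 list as the highest other, whereas its 15 lists with the preset correlation were reached by 6 of 21 (highest other 17). RNA from other cells stays open as a part of the cause: 480 of the 777 genes were still called with the marker level of all other cell types as a covariate, but 171 with that of macrophages, whose level was 6.42 log2 CPM in core and 4.66 in rim. Whether 1 WT rim library carries the pattern stays open too, with 68 genes called without H874 and 687 without H877 (349 among the 777), and while the deviations of H874 and H877 from separate subsets of WT core correlated at a mean of 0.324 across 10404 genes, WT core F164 and H876 reached 0.342. A difference in T cell state between sites, which the design names, is consistent with these values and was not tested apart from the animals that gave the tissue.

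The inhibitory receptor list was higher in KO rim than in WT rim, with a mean log2 fold change of 1.53. It kept a mean of 1.35 with the covariate for macrophage markers, at least 1.3 without either WT rim library and 1.55 among female libraries. These sizes argue against macrophages, a single WT rim library or sex as the whole cause. The camera calls with the covariate and among female libraries add little. They used the preset correlation, with which the other splits of rim gave a median of 13 lists. The covariate for all other cell types (1.42) tests little, since that level hardly differed in rim, but KO rim F322 and F86 had fewer macrophage transcripts (4.43 and 3.25 log2 CPM) than H874 and H877 (4.54 and 4.79) and more Pdcd1. The 15 splits of the 6 rim libraries cannot give a share under 0.05: 3 lists passed with an estimated correlation in the real split and 2 at most in another (1 of 15 as high), but 4 by fry against a highest other of 5 (2 of 15), 14 with the preset correlation against 18 (7 of 15) and 0 genes against 26 (KO rim F15 and O set against the rest, which points to a structure of the samples), and 1480 genes at an unadjusted p under 0.05 were matched by 5 of 15 splits, with 2278 as the highest other. Loss of endothelial PD-L1 may accompany a higher inhibitory receptor level in rim CD8 T cells, as a hypothesis that 2 WT libraries leave open.

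B and plasma cell markers were lower in KO core, with a mean log2 fold change of -0.898, but not with an estimated correlation (adjusted p = 0.727) or by the mean level per library (exact permutation p = 0.115, adjusted p = 0.315). Within groups, 55 pairs of the 11 measured markers correlated across libraries at a median of 0.783, where random gene sets of matched level had a 95th percentile of 0.0984, which is consistent with B cells carried through the CD8 sort in varying number. None of the 11 markers is on another list, and Cd79a reached 54.8 CPM in WT core and 24.1 CPM in KO core. No single library made the difference, since the mean stayed at -0.548 or further below 0 (adjusted p = 0.000124 without WT core H876). The fall was not general in KO core, however. The mean level of the list was 1.92 log2 CPM in KO core F319, 2.68 in F86 and 2.5 in O. It was 5.08 in F219, 4.91 in F318 and 5.34 in F322, within the 4.23 to 6.16 of the WT core libraries. Whether tumours of KO mice hold fewer B cells was not tested.

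For KO against WT in core no gene was called, a count that any split reaches (100 of 100), so that it tests nothing. The highest of the 99 other splits drawn called 119 genes and put WT core F164, H873, H876 and the pool with KO core F219. It differs from the grouping by genotype in the exchange of F219 and H719 alone, and points to a structure of the samples whose cause was not tested. Without H719 the genotype test itself called no gene, with 1552 at an unadjusted p under 0.05 and a smallest adjusted p of 0.168. The 1244 genes at an unadjusted p under 0.05 were reached by 37 of 100 splits (highest other 2055) and the 10 lists called with the preset correlation by 43 of 100 (highest other 16), so that chance is not excluded for either. For core against rim in KO, 0 genes were called, which again any split reaches (100 of 100, highest other 2), while 1600 genes at an unadjusted p under 0.05 were reached by 4 of 100 splits. The other 3 of these gave more than the real one (highest other 2096). The share lies under 0.05 by a narrow margin and for that count alone. It rests on 100 drawn of the 210 splits of core against rim in KO, so that chance is not firmly excluded. The 10 lists called there were reached by 50 of 100 (highest other 16). Arbitrary splits thus gave 8 to 13 lists as a median with the preset correlation, and 0 with an estimated one.

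The effect of genotype differed between core and rim by camera's test of the difference with the preset correlation for 14 lists, given here as the median difference, core minus rim, with the adjusted p with an estimated correlation. Inhibitory receptors stood at -1.48 (adjusted p = 0.0296), effector cytokines at -0.878 (0.0303), T cell receptor response genes at -0.561 (0.0303) and CD4 and regulatory T cell markers at -1.26 (0.0303). The rest passed with the preset correlation alone. Exhaustion-associated transcription factors stood at -0.358 (adjusted p = 0.14 with an estimated correlation), residency genes at -0.394 (0.144), co-stimulatory receptors at -0.5 (0.211), cell cycle genes at -1.38 (0.0697), glycolysis genes at -0.442 (0.129), oxidative phosphorylation genes at -0.162 (0.54) and terminal effector genes at 0.91 (0.129). Macrophage markers stood at -1.73 (0.468), neutrophil markers at -1.71 (0.54) and fibroblast markers at -1.47 (0.508). The mean difference of terminal effector genes fell from 1.01 to 0.0983 without WT rim H877. That of residency genes went from -0.561 to -0.247 without WT rim H874. The difference holds the same 2 WT rim libraries as the rim comparison and is not a separate finding. For the inhibitory list the mean log2 fold change of KO over WT was -0.292 in core and 1.53 in rim. Group labels were not exchanged for the difference. With the preset correlation, other splits gave up to 16 lists for KO against WT in core and 18 in rim.

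A library stood apart from the rest of its group in 7 of 117 tests over 39 measures, where chance gives about 1 in 20. The cytotoxic list was low in WT core F164, at a mean of 6.95 log2 CPM against 7.25 to 7.37 in the others. Chemokine receptors were high in the WT core pool, at 7.75 against 7.35 to 7.46. The interferon gamma list was low in KO core F319, at 7.24 against 7.65 to 7.78, and in KO rim F322, at 7.32 against 7.59 to 7.65. Red blood cell markers were low in KO core F318, at -3.11 against 1.53 to 3.11. Pdcd1 was low in KO core F318, at 8.33 log2 CPM against 9.76 to 10.5. Mki67 was high in KO core F86, at 7.93 log2 CPM against 6.43 to 6.95.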

How the results depend on the processing

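The fits of female libraries alone and with macrophage markers as a covariate were chosen after seeing the data; the other alternatives were planned. With DESeq2 size factors all counts of called genes stayed within 1.5 times and all 63 list calls were kept. By the DESeq2 Wald test 12 genes were called for KO against WT in core, 272 in rim, 33 for core against rim in KO, 1853 in WT and 159 for the difference of genotype effects. Without a filter, rim gave 2 genes (Npl and Glp1r) and the difference 4 (Npl, Xcl1, Glp1r and Kntc1). With a filter at 5 CPM, rim gave 9 and the difference the same 4, with fewer genes tested. With the identifier as a random block in limma voom, whose consensus correlation was 0.0425, rim gave 8 genes and core against rim in KO 2 (Trpa1 and Rbms3). Core and rim libraries of KO were also correlated on log2 CPM less the group mean of each gene, without sex-linked genes. On this measure libraries that share an identifier correlated at 0.0622 for F322, 0.0407 for F86 and 0.0734 for O, against -0.198 to 0.24 between identifiers. All 3 of these core libraries correlated best with their own identifier in rim, and 1 of the 3 rim libraries with its own in core, and sex matched within each identifier, a hint from the data and not the design. The 6 KO libraries with shared identifiers gave 0 genes with a fixed block and 0 without. With quality weights rim gave 6, core against rim in KO 2 (Trpa1 and Rbms3) and in WT 139. With sex as a covariate rim and the difference each gave 1 (Tnfsf4). Core against rim in WT gave 91 in a fit of its 2 groups, 313 among female libraries and 183 with the macrophage covariate. All genes named here were chosen after their values were seen, and the cause was not tested.

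Leaving out each library in turn, the count stayed at 0 in all 11 fits of KO against WT in core and all 10 of core against rim in KO. It ran from 0 to 26 for KO against WT in rim, from 68 to 795 for core against rim in WT and from 0 to 14 for the difference. The rim count was 4 without WT rim H874 (Spn, Cenpf, Cracdl and Gart). The difference gave 5 without WT rim H874 (Gart, Cenpf, Cracdl, D630039A03Rik and Ptpn5), 5 without WT core H876 (Glp1r, Nrgn, Npl, Kntc1 and Xcl1), 2 without the pool (Npl and Tnfsf4) and 1 without KO core F86 (Clgn), all chosen after their values were seen. Where WT rim is left with 1 library, that library is assumed to vary like the other groups. The filter also kept more genes there, 23546 without H874 and 23367 without H877 against 20137 in the main fit. The correlation of genotype effects across genes was 0.0312, and 0.0961 at a mean of at least 5 CPM. The planned correlation over genes called in either genotype comparison gave no value, since edgeR called none there (1244 genes at an unadjusted p under 0.05 in core and 1480 in rim). The level over all markers of other cell types kept its direction with a median over the list in all 4 comparisons. Among single lists in core, CD4 and regulatory T cell markers lost their call (adjusted p of 0.0433 by the mean and 0.453 by the median, exact permutation test), and dendritic cell markers turned from -0.296 to 0.0167.

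Of the 63 list calls, 54 kept with a filter at 5 CPM, 61 without a filter, 55 with a random block, 55 with quality weights, 56 with the marker covariate, 51 with the macrophage covariate, 58 with sex and 56 among female libraries. Both marker covariates are made from lists that are themselves among the calls, and a call of such a list lost with them decides nothing. In fits of 2 groups 46 of 49 kept, and 12 of 63 with an estimated correlation and 18 of 63 by fry. Camera's direction reversed for some lists, given here with their mean log2 fold change, and the cause was not tested. Co-stimulatory receptors for core against rim in KO turned to 0.0571 with a fixed block and 0.0577 without on the 6 libraries, and ribosomal protein genes in core to 0.0604 among female libraries. With the macrophage covariate neutrophil markers turned to -0.908 for KO against WT in rim, -0.441 for core against rim in WT and 0.531 for the difference. Leaving out a library also turned the direction of some. For KO against WT in rim, stem-like genes ran from -0.616 (without WT rim H877) to 0.507 (without H874), ribosomal protein genes from -0.604 (without H877) to 0.476 (without H874) and cytotoxic genes from -0.195 (without KO rim O) to 0.596 (without H877). For core against rim in WT, cytotoxic genes ran from -0.0776 (without H874) to 0.503 (without H877), and ribosomal protein genes reached 0.525 (without H874). For the difference, cytotoxic genes ran from -0.396 (without H877) to 0.255 (without KO core F319), ribosomal protein genes from -0.556 (without H874) to 0.524 (without H877) and dendritic cell markers from -1.76 (without H877) to 1.28 (without WT core H876). On simulated data edgeR recovered 17 of 50 genes changed 4-fold with the rim group sizes and 23 of 45 with the core group sizes. Of genes changed 16-fold it recovered 24 of 45 and 31 of 46. Among those with a mean of at least 5 CPM it recovered 24 of 30 and 26 of 28. Large changes can thus be missed too at these sizes and depths, above all in genes of low level.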
